A study of Mus musculus with 6 samples.

How the data were processed

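Total RNA of cultured mouse aortic smooth muscle cells was sequenced in 6 libraries, 3 with vehicle and 3 with TWEAK, and the series' design text names a stranded Illumina total RNA kit. The authors deposited 1 table of 14927 gene symbols. Per the submitters' processing notes DESeq2 was used, with no version named; the aligner, the read counter, its use of strand, the genome build and the annotation are not given in the sources used here, and no coordinates are printed. Counts of near-identical relatives, such as the Serpina3, histone, Gbp and class I H2 genes, and of overlapping or antisense genes are therefore uncertain.

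The deposited table holds, per the file headers, the authors' mean of the normalized counts, the log2 fold change and its standard error, the Wald statistic (a score), the p-value and the adjusted p-value, and 1 column of normalized counts per library. The normalized counts are a signal made by the authors from read counts divided by 1 size factor per library. In every column the values are whole multiples of the value of 1 read, and 100% of them came out whole within a tolerance of 0.01, so the reads were recovered: 62632273 to 82118717 per library over the listed genes. The smallest mean is 14.4, no value is 0 and no mitochondrially encoded gene is listed, so a list of those genes was not tested. Each library's columns were matched to its sample by the treatment and the experiment number in the header, taken as the replicate number of the sample title.

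All values were compared on log2(normalized count + 1) for genes with a mean of at least 1, which kept all 14927. The test was limma 3.58.1 in R 4.3.3 with empirical Bayes, an intensity trend and robust estimation, two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The design fixed before the data were examined was unpaired, with a fit using the replicate number as a block as an alternative. Whether the numbers pair the samples was then checked from each library's deviation from its group mean. Across genes these deviations correlated at 0.879, 0.868 and 0.734 for libraries with the same number (genes are not independent replicates). For libraries with different numbers the correlations lay between -0.760 and -0.126. Deviations from a group mean cancel within the group, so these negative values follow in part from the positive ones. The first principal component also separated the numbers, and 7251 genes differed among experiments at a limma adjusted p under 0.05. The pairing therefore comes from the experiment numbers in the column headers and these correlations, and the blocked values are printed, with unpaired ones beside the counts of genes and beside some genes and lists; of the genes named, 3 passed unpaired. A DESeq2 1.42.0 fit with the block to the recovered reads called 2702 genes, as many as the authors' deposited table, 2666 of them shared, and its log2 fold changes correlated with those of the table at r = 1.00 across genes; without the block it called 752. The authors' model formula is not given in the sources used here.

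No pair of libraries was a duplicate: the lowest chi-square per degree of freedom of any 2 libraries was 90.7. Single values per library were compared with a two-sided exact permutation test, whose smallest p is 0.1 for 3 against 3.

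The genes named were fixed by a rule before the data were examined. It took Tnfrsf12a, Tnfsf12, Ccnd1, Cdk4, Cdk6 and Cdkn2b always. It then took the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap, whose mean was at least 5 and whose symbol is not that of an unnamed gene model. Of each gene list it took up to 4 called members with the smallest adjusted p, or the 2 most abundant where none was called. The rule was applied to both fits. Unpaired, it named Mmp9, Col6a4 and Ccl7 and otherwise the most abundant members of each list, of which those informative about a list are given. Some genes that the rule named are not reported here. Groups did not overlap for 2391 genes, 16.0% of those tested, where chance gives 10% for 3 against 3 exchangeable libraries, which libraries paired by experiment are not, and for 1244 of the called genes. Genes outside the rule are said to be chosen after their values were seen.

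There were 34 gene lists, written from textbook knowledge before the data were examined, and 33 had at least 3 measured members. They were tested with camera at a preset correlation of 0.01, adjusted over the 33 lists, and 18 passed blocked, 9 up and 9 down, as did 18 unpaired. With the correlation estimated from the data, 1 list (mitosis) passed unpaired and none blocked, the smallest blocked adjusted p being 0.245. With fry, which tests whether the members of a list move, on balance, one way, 17 lists passed blocked, not all of them the same lists. The collagen (fry adjusted p = 0.0747), complement (0.193), cholesterol (0.0799), unfolded protein response (0.0846) and ribosomal (0.178) lists passed blocked camera and not fry. The TWEAK axis (0.0206), leukocyte adhesion (0.0498), matrix protease (0.0256) and osteochondrogenic (0.00895) lists passed fry and not blocked camera.

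The steps were tested on simulated reads for the 14927 genes with 200 genes changed. Both simulated libraries of an experiment started from the levels of its own vehicle library. Pairing was thus built in, and the simulated reads cannot show whether the block suits the real ones. The blocked limma fit recovered 60% of genes changed 1.5-fold, 81% of those changed 2-fold and 100% of those changed 4-fold, with 15 false calls among 176. The unpaired fit recovered 0% and 0% of the genes changed 1.5-fold and 2-fold and 18% of those changed 4-fold, with no false call among 9. In the simulated lists, camera at the preset correlation called the planted list and none of the unchanged ones. Fry with the block also called 1 unchanged list, and in camera with an estimated correlation and the block the planted list had an adjusted p of 0.0903. The simulated genes varied independently, so false calls of the preset correlation in lists whose genes move together were not tested.

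Alternatives were other filters (none, a mean of at least 5 or 50), pseudocounts of 0.1 and 5, cyclic loess and median-ratio scaling, edgeR 4.0.16 with 3 normalizations, DESeq2 and limma-voom on the recovered reads, other thresholds, leaving out each library or each experiment, and a correction for GC content and transcript length. That correction took a spline fit with 5 degrees of freedom each out of every library. GC content and length came from GENCODE vM21 transcripts matched by symbol for 14783 genes (99.0%), 769 of them through an older symbol. The mean of at least 50, that correction, and every alternative under the block were chosen after seeing the data.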

Results

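RNA was sequenced from cultured vascular smooth muscle cells isolated from the aortas of wild-type C57BL/6 mice. Smooth muscle cells form the contractile layer of the artery wall and can leave that state to divide and secrete matrix. The cells were held in 0.5% serum for 24 h and then given either vehicle or 100 ng/mL recombinant TWEAK for a further 24 h. TWEAK, encoded by Tnfsf12, is a cytokine of the tumour necrosis factor superfamily that binds the receptor Fn14, encoded by Tnfrsf12a. There were 3 vehicle libraries and 3 TWEAK libraries, numbered 1 to 3 in each group, and the column headers of the deposited table give these numbers as experiments. The table lists 14927 genes by symbol, each with at least 1 read in every library. Reads summed over these genes ranged from 62632273 to 82118717 per library. The group means were 69827451 ± 6136278 reads with vehicle and 72757591 ± 9765673 with TWEAK (SD, n = 3; two-sided exact permutation p = 0.8, where 3 against 3 cannot go below 0.1). The 100 most abundant genes took 18.1% ± 0.620 of the reads with vehicle and 16.4% ± 0.739 with TWEAK (SD, n = 3). The exact permutation p was 0.1, or 0.3 adjusted over the library measures. An exact test that flips signs within experiments gave p = 0.25, the smallest that 3 pairs allow. Nothing in the labels says whether the experiments used cells from separate animals. With the experiment as a block, limma's p-values measure how the difference between TWEAK and vehicle varied among these 3 experiments. Unpaired p-values measure the spread between the libraries of a group. Either spread may be technical.

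The first principal component held 56.2% of the variance and set the experiments apart, while on the second, with 22.2%, each TWEAK library lay above the vehicle library of its own experiment. The macrophage gene Lyz2, which encodes lysozyme, had 35968 normalized counts in the vehicle library of experiment 1 and 1866 in that of experiment 3. Pecam1, an adhesion molecule of endothelial cells, had 2253 normalized counts in the vehicle library of experiment 1 and 20068 in that of experiment 2. Both genes differed among experiments (limma adjusted p = 0.000256 for Lyz2 and 0.000342 for Pecam1), and neither passed limma's test between treatments, blocked or unpaired, though Pecam1 was called after the GC and length correction. Changes within experiments are therefore given first below.

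**Figure D1:**
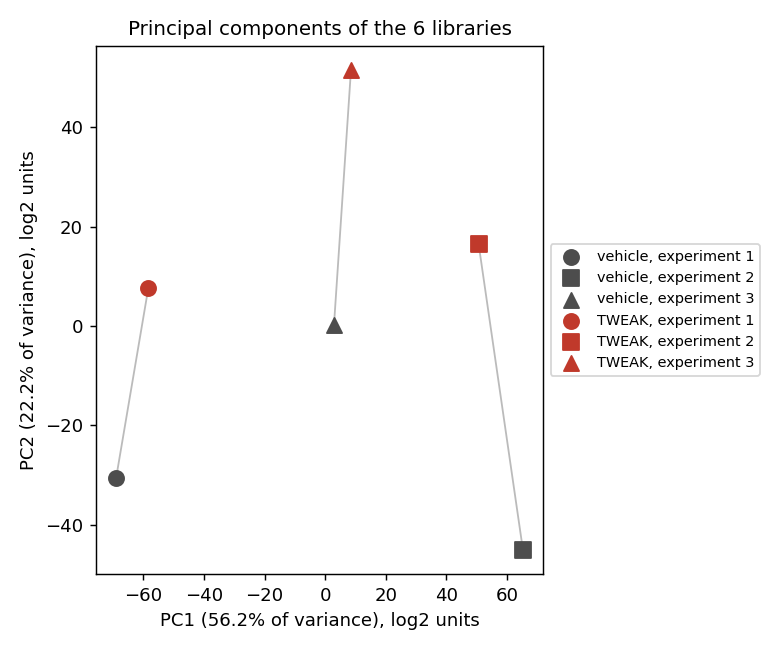
Principal components of log2(normalized count + 1) over 14927 genes, in log2 units, with each point a library, colour marking the group, shape the experiment, and a line joining both libraries of one experiment. PC1 (56.2% of variance) separates the experiments, and the TWEAK library lies higher on PC2 (22.2%) than its vehicle partner in all 3 experiments.

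The comparison asks which transcripts of these smooth muscle cell cultures change after TWEAK. The title of the series places TWEAK and Fn14 in restenosis, the renewed narrowing of a widened artery. Since the cultures also held macrophage and endothelial transcripts, the cells in which a gene changed cannot be read from bulk RNA. Within experiments, all 37 listed genes of mitosis, 34 of 38 of DNA replication, 13 of 19 chemokines, 15 of 26 NF-kB genes and 30 of 34 interferon-response genes rose with TWEAK, and 20 of 28 contractile genes fell. These lists passed a list test, camera, with a preset correlation between genes. Blocked and with an estimated correlation they did not (camera adjusted p = 0.245 for mitosis and 0.292 for the others). In simulated reads a planted list of changed genes did not pass that blocked test either (camera adjusted p = 0.0903). Failing it therefore does not show that a list was unchanged. Mmp9, a gelatin-degrading matrix protease, rose most among the genes whose groups did not overlap, from 10.7 ± 2.87 to 1080 ± 270 normalized counts (SD, n = 3), a 92.2-fold rise. Ccl7, a chemokine that attracts monocytes, rose 6.57-fold from 2652 ± 584 to 17168 ± 589, and Myh11, the smooth muscle myosin heavy chain, fell 2.20-fold from 27729 ± 10124 to 13042 ± 6533. With the experiment as a block, limma called 2039 genes at a Benjamini-Hochberg adjusted p under 0.05, of which 1210 were higher and 829 lower with TWEAK. All 2039 moved the same way in the 3 experiments, which selection by a test on these same differences makes likely. Of the 595 called genes that changed by at least 1 on the log2 scale, 460 were higher and 135 lower. Without the block, 3 genes passed: Mmp9 (adjusted p = 0.00862), Ccl7 (0.0357) and Col6a4 (0.0441), a collagen VI chain; all 3 rose, and 1480 genes had an unadjusted p under 0.05. The authors' deposited table, from DESeq2, has 2702 genes at an adjusted p under 0.05, 1611 higher and 1091 lower, and shares 2010 of them with the blocked limma fit.

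Correcting each library for GC content and transcript length gave 4175 genes in the blocked fit, 1789 higher and 2386 lower. Leaving out experiment 1, 2 or 3 gave 695, 3902 and 666. Every call named below is from the blocked limma fit unless the unpaired fit is named, and fold changes are on the log2(normalized count + 1) scale, which understates the change of low genes.

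The receptor gene Tnfrsf12a was among the genes that fell. Its mean went from 8281 ± 1887 to 6180 ± 1211 normalized counts (SD, n = 3), and its log2 fold change was -0.42 (SE 0.09, limma adjusted p = 0.0407; 0.678 unpaired). It fell by 0.21, 0.48 and 0.56 on the log2 scale in experiments 1, 2 and 3. The call was lost with edgeR and with limma-voom on the recovered reads. For the ligand gene Tnfsf12 the log2 fold change was -0.26 (SE 0.09, adjusted p = 0.111). Of the 3 listed genes of the TWEAK axis, 1 fell over all genes and 2 fell when adjusted over the list alone, and the list did not pass camera, limma's test of a gene list against the other genes (adjusted p = 0.112).

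Among the 12 largest rises whose groups did not overlap, Mmp9 was followed by Spib, a transcription factor of the ETS family, with a log2 fold change of 5.71 (SE 0.85), and Sohlh2, a transcription factor of germ cells, with 5.01 (SE 0.52). The chemokines Cxcl10 (4.60), Ccl20 (4.37) and Cxcl9 (3.93) were in this group, as were Madcam1 (4.55), an adhesion ligand for leukocytes, and the protease inhibitors Serpina3g (4.50) and Serpina3f (4.15). Col6a4 (4.02), the leukocyte receptor gene Slamf8 (3.84) and Hhip (3.78), a hedgehog-binding protein, completed it. Vehicle levels were low and varied for Sohlh2 (7.21 ± 7.12 normalized counts), Serpina3f (8.34 ± 10.7) and Hhip (15.6 ± 12.6; SD, n = 3). The sizes of these 3 folds are therefore uncertain. The adjusted p-values of these 12 genes in limma ran from 0.00276 for Mmp9 to 0.0314 for Hhip. Some were uneven, and leaving out 1 experiment moved their folds by over 1.5 times. Without experiment 1 the log2 fold change was 7.06 for Spib, 5.28 for Madcam1, 4.62 for Slamf8 and 2.64 for Hhip; without experiment 2 it was 5.07 for Spib, 4.77 for Serpina3f and 4.40 for Hhip; and without experiment 3 it was 5.01 for Spib, 5.74 for Sohlh2 and 3.37 for Serpina3f.

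Among called genes whose groups did not overlap, the largest fall was that of Lrtm1, which encodes a leucine-rich repeat membrane protein, from 2339 ± 1394 to 193 ± 87.9 normalized counts (SD, n = 3). Its log2 fold change was -3.54 (SE 0.20, limma adjusted p = 0.00295; 0.125 unpaired). Ccdc42 (-3.22), Ecel1 (-2.81), Ntng1 (-2.60) and Ccrl1 (-2.51), a scavenging chemokine receptor, came next. Pmp2 (-2.18), a myelin lipid-binding protein, Adamts17 (-2.04), Susd5 (-2.03) and the ephrin receptor gene Epha5 (-2.01) followed. Aldh1a7 (-1.92), Rasgrp2 (-1.90) and Acta1 (-1.84), skeletal muscle alpha-actin, were the smallest of these 12 falls. The call of Epha5 was lost with edgeR and limma-voom on the recovered reads, and its log2 fold change was -1.42 without experiment 1.

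All 37 measured genes of G2 phase and mitosis rose, over all genes and adjusted over the list alone, with a median log2 fold change of 1.10. The cyclin gene Ccna2 went from 3273 ± 325 to 7632 ± 256 normalized counts (SD, n = 3; log2 fold change 1.23, SE 0.08). The spindle checkpoint kinase gene Bub1b (1.24), the kinetochore gene Cenpf (1.20) and the spindle motor gene Kif2c (1.13) rose by similar amounts, as did Top2a (1.37), which untangles replicated DNA, and Mki67 (1.48), the Ki-67 proliferation antigen. The list passed camera with the preset correlation (adjusted p = 6.65e-27 blocked, 1.5e-27 unpaired). With an estimated correlation the adjusted p was 0.245 blocked and 0.00652 unpaired. Unpaired, 26 of the 37 passed when adjusted over the list alone.

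Of 38 genes of G1/S and DNA replication, 34 rose and none fell (2 fell after the GC and length correction), with 4 that did not pass, and the median log2 fold change was 0.99. Adjusted over the list alone, 35 rose and 2 fell, and 30 passed unpaired. Pole, a replicative DNA polymerase subunit, rose by 1.16 (SE 0.07), while Uhrf1, which maintains DNA methylation, rose by 1.23 (SE 0.09). By camera this list passed (adjusted p = 6.38e-20), and the adjusted p = 0.292 with an estimated correlation. Of the G1 genes fixed in advance, Cdk6 rose by 1.08 (SE 0.08, limma adjusted p = 0.00335; 0.168 unpaired), Ccnd1, cyclin D1, by 0.67 (SE 0.12, 0.0250; 0.181 unpaired) and Cdk4 by 0.31 (SE 0.06, 0.0307; 0.832 unpaired). Ccnd2, cyclin D2, had a log2 fold change of -0.26 (adjusted p = 0.0690) and was called with edgeR and upper quartile scaling and after the GC and length correction. Of 8 CDK inhibitor genes, Cdkn2b (p15) fell by 0.53 (SE 0.08, adjusted p = 0.0127; 0.279 unpaired) and Cdkn2c (p18) rose by 0.40, and 6 did not pass, among them Cdkn1a (p21) at -0.12. Adjusted over the list alone, 2 rose and 1 fell, and the list did not pass camera (adjusted p = 0.502).

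Replication-dependent histone genes, whose transcripts lack poly(A) tails and are made in S phase, rose for 14 of 15 members, also adjusted over the list alone, with a median log2 fold change of 1.03. Hist1h1a rose 3.10-fold, Hist1h1b 2.94-fold, Hist1h3a 2.78-fold and Hist1h1d 2.14-fold. The list passed camera (adjusted p = 1.95e-11), with an adjusted p = 0.292 with an estimated correlation. Reads of near-identical histone genes could have been shared, since how they were counted is not given in the sources used here.

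Chemokine genes rose for 13 of 19 measured members and fell for none (1 fell in the authors' table, with cyclic loess and after the GC and length correction), with a median log2 fold change of 2.30. Adjusted over the list alone, 15 rose and 1 fell. Cxcl10, a ligand of T cells' CXCR3 receptor, went from 64.3 ± 34.3 to 1548 ± 627 normalized counts (SD, n = 3), and Cxcl9, a ligand of the same receptor, from 12.7 ± 4.05 to 202 ± 32.3. Ccl20 went from 25.2 ± 9.40 to 531 ± 158. Ccl2, the monocyte chemokine MCP-1, chosen after its values were seen, rose 5.56-fold to 28068 ± 5877 and varied between experiments, with log2 ratios of 3.65, 1.63 and 2.14 and a log2 fold change of 1.89 without experiment 1; its call was lost with edgeR and upper quartile scaling and after the GC and length correction. In camera the list passed (adjusted p = 1.50e-08 blocked, 3.05e-13 unpaired), and the adjusted p = 0.292 with an estimated correlation.

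Of 26 genes encoding NF-kB components and feedback targets, 15 rose, 11 did not pass and none fell, with a median log2 fold change of 0.78; adjusted over the list alone, 21 rose. Nfkb2, the precursor of p52 in the non-canonical pathway, rose 3.52-fold from 4710 ± 1199 to 16449 ± 3504 (SD, n = 3), with log2 ratios of 1.88, 1.75 and 1.82 in the 3 experiments. Traf1, an adaptor of TNF receptors, rose 5.94-fold, Nfkbie, an inhibitor of NF-kB, 5.48-fold, and Birc3, a ubiquitin ligase and inhibitor of apoptosis, 4.43-fold. The list passed camera (adjusted p = 2.19e-12), with an adjusted p = 0.292 with an estimated correlation.

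Interferon-response genes rose for 30 of 34 members and fell for none (1 fell in the authors' table, with cyclic loess and after the GC and length correction), with a median log2 fold change of 1.01; adjusted over the list alone, 32 rose and 1 fell. Ifi44 rose 3.47-fold, Oasl2 2.92-fold, Rtp4 2.66-fold and Irf1, a transcription factor of this response, 2.39-fold. The camera adjusted p was 3.04e-19, and the adjusted p = 0.292 with an estimated correlation. Of 18 genes of class I antigen presentation, 12 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.62. H2-Q4, a class I gene, rose 3.70-fold, the immunoproteasome genes Psmb8 and Psmb10 rose 3.17-fold and 2.37-fold, and H2-K1 rose 1.96-fold. Calr, an endoplasmic reticulum chaperone named after its value was seen, fell by 0.23 on the log2 scale and lost its call with cyclic loess, edgeR and DESeq2. By camera this list passed (adjusted p = 2.97e-08), and the adjusted p = 0.301 with an estimated correlation.

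Of 17 cytokine and colony stimulating factor genes, 5 rose and 3 fell (9 and 3 adjusted over the list alone, 8 and 4 after the GC and length correction). Il6 rose 2.18-fold and Lif 1.47-fold, while Il11 fell 1.71-fold and Clcf1 1.57-fold; the list did not pass camera (adjusted p = 0.134). Of 10 leukocyte adhesion genes, 4 rose and 1 fell, also adjusted over the list alone. Madcam1, at 7.58 ± 4.87 normalized counts with vehicle and 268 ± 242 with TWEAK (SD, n = 3), rose with Icam1 (2.34-fold), Vcam1 (1.87-fold) and the hyaluronan receptor gene Cd44 (1.58-fold), and Mcam fell 1.55-fold. The adhesion list passed camera unpaired (adjusted p = 0.0350) and not blocked (0.112), and the adjusted p = 0.340 unpaired with an estimated correlation. Of 15 complement and acute phase genes, 3 rose, also adjusted over the list alone: C3, the central complement component, 9.63-fold from 3476 ± 1932 to 31739 ± 12108, Cfb 2.50-fold and Cp 1.61-fold; the call of C3 was lost with edgeR and upper quartile scaling, and its log2 fold change of 3.27 was 2.66 without experiment 3. After the GC and length correction 5 rose. That list passed camera (adjusted p = 0.00781), and the adjusted p = 0.506 with an estimated correlation.

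**Figure D2:**
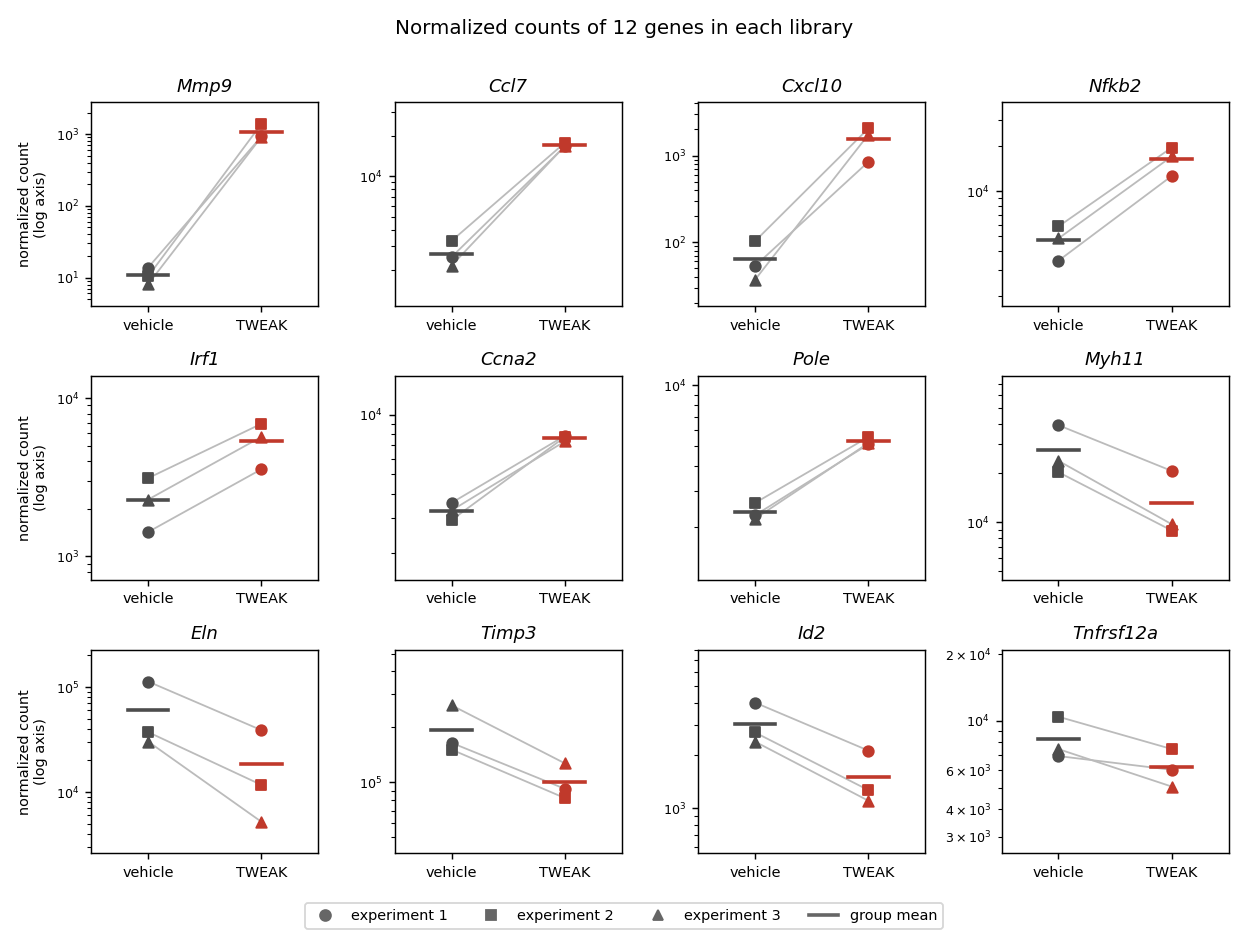
Normalized counts (log axis) of 12 genes in each library, with points marking libraries, shape the experiment, lines joining both libraries of one experiment and bars the group means (n = 3). Mmp9 went from a mean of 10.7 to 1080 and Myh11 from 27729 to 13042, and each of the 12 genes moved the same way in all 3 experiments.

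Smooth muscle contractile genes fell for 20 of 28 members, rose for 3 and did not pass for 5, with the same counts adjusted over the list alone and a median log2 fold change of -0.56. Myh11 fell by 1.14 (SE 0.09, limma adjusted p = 0.00355; 0.426 unpaired), Ppp1r14a, an inhibitor of myosin phosphatase, by 0.94, and Mylk, myosin light chain kinase, by 0.57. Acta2, smooth muscle alpha-actin, fell by 0.55, from 179848 ± 13225 to 124067 ± 20128 normalized counts (SD, n = 3). Cnn1 (-1.10) and Tagln (-0.53), both actin-binding proteins, were chosen after their values were seen. The 3 that rose were Synm (0.94) and, named after their values were seen, Des (0.96) and Synpo2 (0.74); Synm and Des encode intermediate filament proteins and Synpo2 an actin-binding protein. The list passed camera (adjusted p = 6.21e-09), and the adjusted p = 0.292 with an estimated correlation. Unpaired, 10 of the 28 passed when adjusted over the list alone.

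Of 30 matrix glycoprotein and crosslinking genes, 11 fell and 2 rose (15 and 3 adjusted over the list alone). Eln, elastin, fell 3.78-fold within experiments, from a mean of 60142 ± 45826 to 18573 ± 17839 (SD, n = 3), and the log2 ratios were -1.54, -1.67 and -2.54. Thbs1, thrombospondin 1, fell 1.44-fold and Tnc, tenascin C, 1.30-fold, while Vcan, the proteoglycan versican, rose 1.56-fold. Fn1, fibronectin, had a log2 fold change of 0.15 (adjusted p = 0.121) and was called only with cyclic loess among 13 blocked alternatives. In camera the list passed (adjusted p = 0.00189) but not after cyclic loess scaling (0.128), which took its median from -0.17 to -0.03, and the adjusted p = 0.292 with an estimated correlation. Of 21 collagen genes, 6 fell and 2 rose (9 and 2 adjusted over the list alone). Col8a2 fell 5.35-fold, Col5a1 1.48-fold, Col4a2 1.24-fold and Col4a1 1.23-fold; the calls of Col4a1 and Col4a2 were lost after cyclic loess scaling. Col1a2 and Col3a1, the most abundant of the list, had log2 fold changes of -0.08 and -0.16 and did not pass, and both values turned positive after cyclic loess scaling, while Col3a1 was called as lower with edgeR and upper quartile scaling and after the GC and length correction. The collagen list passed camera blocked (adjusted p = 0.00302) and not unpaired (0.0661) or after cyclic loess scaling (0.463), which took its median from -0.15 to -0.01, and the adjusted p = 0.306 blocked with an estimated correlation.

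Of 28 matrix protease and inhibitor genes, 6 rose and 4 fell (10 and 8 adjusted over the list alone, 9 and 7 after the GC and length correction). Besides Mmp9, Mmp8 rose 3.51-fold, and, chosen after their values were seen, the stromelysins Mmp3 and Mmp10 rose 6.20-fold and 6.08-fold. Timp3, an inhibitor of matrix proteases, fell from 191810 ± 60873 to 100081 ± 23382 normalized counts (SD, n = 3; limma adjusted p = 0.00307; 0.302 unpaired). The median of this list was -0.07 and its mean 0.54, and camera gave an adjusted p = 0.827. Of 25 genes listed under TGF-beta, SRF or YAP signalling, 11 fell and 1 rose, also adjusted over the list alone. The list also holds ligands, receptors and Id genes, which BMP signalling induces, so it does not measure the response to 1 pathway. Tgfb3, a TGF-beta ligand, fell 2.09-fold, Id2 2.06-fold and Id3 1.67-fold, both inhibitors of DNA binding. Ctgf, connective tissue growth factor, fell by 0.68 on the log2 scale, and Ltbp2, a matrix protein that binds fibrillin, rose 1.64-fold. The list passed camera (adjusted p = 0.00433), and the adjusted p = 0.301 with an estimated correlation.

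Of 28 growth factor and receptor genes, 3 rose and 5 fell (4 and 8 adjusted over the list alone, 4 and 9 after the GC and length correction). Vegfc, a lymphatic growth factor, rose 3.07-fold and Pdgfra, a PDGF receptor, 2.70-fold, while Igfbp4, which binds insulin-like growth factors, fell 2.20-fold and Bdnf 1.30-fold; the list did not pass camera (adjusted p = 0.134). Of 23 apoptosis and p53 target genes, 6 rose and none fell (9 and 1 adjusted over the list alone, 8 and 1 after the GC and length correction), among them Casp4 (3.48-fold), Casp8 (1.52-fold) and Mdm2 (1.28-fold). That list passed camera (adjusted p = 0.00182), and the adjusted p = 0.292 with an estimated correlation. Of 18 genes of the unfolded protein response, 3 fell and none rose (8 and 0 adjusted over the list alone, 11 and 0 after the GC and length correction): Atf3 1.78-fold, Trib3 1.71-fold and Xbp1 1.25-fold, whose call was lost with edgeR and limma-voom. The camera adjusted p was 9.55e-05, and the adjusted p = 0.306 with an estimated correlation. Of 20 immediate early genes, 5 fell and 2 rose (9 and 2 adjusted over the list alone, 8 and 3 after the GC and length correction), with Fos falling 1.54-fold, Klf2 1.66-fold and Myc rising 1.63-fold. This list passed camera unpaired (adjusted p = 0.0208) and not blocked (0.0502), and the adjusted p = 0.532 unpaired with an estimated correlation.

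Of 18 cholesterol biosynthesis genes, 3 fell, also adjusted over the list alone, and 8 after the GC and length correction, with Sqle 1.29-fold and Fdps 1.18-fold lower, and the call of Fdps was lost in 5 of 13 blocked alternatives. That list passed camera (adjusted p = 0.00456), and the adjusted p = 0.301 with an estimated correlation. In glycolysis and hypoxia, 1 of 22 rose, Pfkfb3 1.29-fold, and 2 fell, Pfkp 1.42-fold and Vegfa 1.50-fold, the same counts as adjusted over the list alone, while 1 and 5 did after the GC and length correction (camera adjusted p = 0.0502). Of 22 oxidative stress genes, 3 rose and 1 fell (4 and 2 adjusted over the list alone, 4 and 7 after the GC and length correction), including the metallothionein Mt2 (2.11-fold) and Gsta4, which fell 1.45-fold (camera adjusted p = 0.390). Of 15 osteochondrogenic genes, 2 rose and 3 fell, also adjusted over the list alone, with the cartilage matrix genes Comp and Acan falling 2.67-fold and 2.28-fold and the phosphate transporter gene Slc20a1 rising 1.82-fold (camera adjusted p = 0.255). Of 12 prostaglandin and nitric oxide genes, 2 rose, Ltc4s 3.46-fold and Ptger4 1.61-fold, its call lost after the GC and length correction (4 adjusted over the list alone; camera adjusted p = 0.390). In Notch signalling, 1 of 14 rose and 3 fell, also adjusted over the list alone: Dtx4 rose 1.36-fold, Lfng fell 1.66-fold, Hey2 1.59-fold and Hes1 1.23-fold, a call lost with edgeR and limma-voom (camera adjusted p = 0.330). None of 31 cytosolic ribosomal protein genes passed in limma, over all genes or adjusted over the list alone, or with edgeR. In limma 0 had an unadjusted p under 0.05, and 4 fell after the GC and length correction. Rplp0 was at -0.09 and Rps2 at -0.08, both positive after cyclic loess scaling. For this list camera gave an adjusted p = 0.00189, but 0.987 after cyclic loess scaling and 0.138 after the GC and length correction. With an estimated correlation the adjusted p was 0.580.

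Markers of other cells that an aortic culture can hold were read as levels in bulk RNA. None of 12 endothelial or 15 macrophage and leukocyte markers passed between treatments, also adjusted over each list alone, with medians of -0.23 and 0.11 (camera adjusted p = 0.112 and 0.336). In limma 6 and 4 of them had an unadjusted p under 0.05, and edgeR on the recovered reads called none. The authors' table has 1 macrophage and leukocyte marker higher, and after the GC and length correction 1 endothelial marker rose and 4 fell and 1 macrophage marker rose. Cdh5 had a log2 fold change of -0.09 and Mpeg1 of 0.27. Of 12 fibroblast and adventitial markers, 2 rose and 3 fell, also adjusted over the list alone (2 and 5 after the GC and length correction): Dpt rose 3.12-fold and Pdgfra 2.70-fold, and Pi16 fell 2.54-fold and Gsn 1.27-fold, whose call was lost with cyclic loess. The median of this list was -0.16 and its mean 0.05 (camera adjusted p = 0.390). Of 5 adipocyte markers 2 fell, also adjusted over the list alone, Plin4 2.22-fold and Pparg 1.85-fold (camera adjusted p = 0.0144; adjusted p = 0.301 with an estimated correlation). Of 9 neural and Schwann markers, S100b fell 2.32-fold and no other passed (1 rose and 3 fell adjusted over the list alone, 1 and 4 after the GC and length correction). That list passed camera blocked (adjusted p = 0.0203) and not unpaired (0.218) or without experiment 1 (0.0883), and the adjusted p = 0.301 blocked with an estimated correlation.

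**Figure D3:**
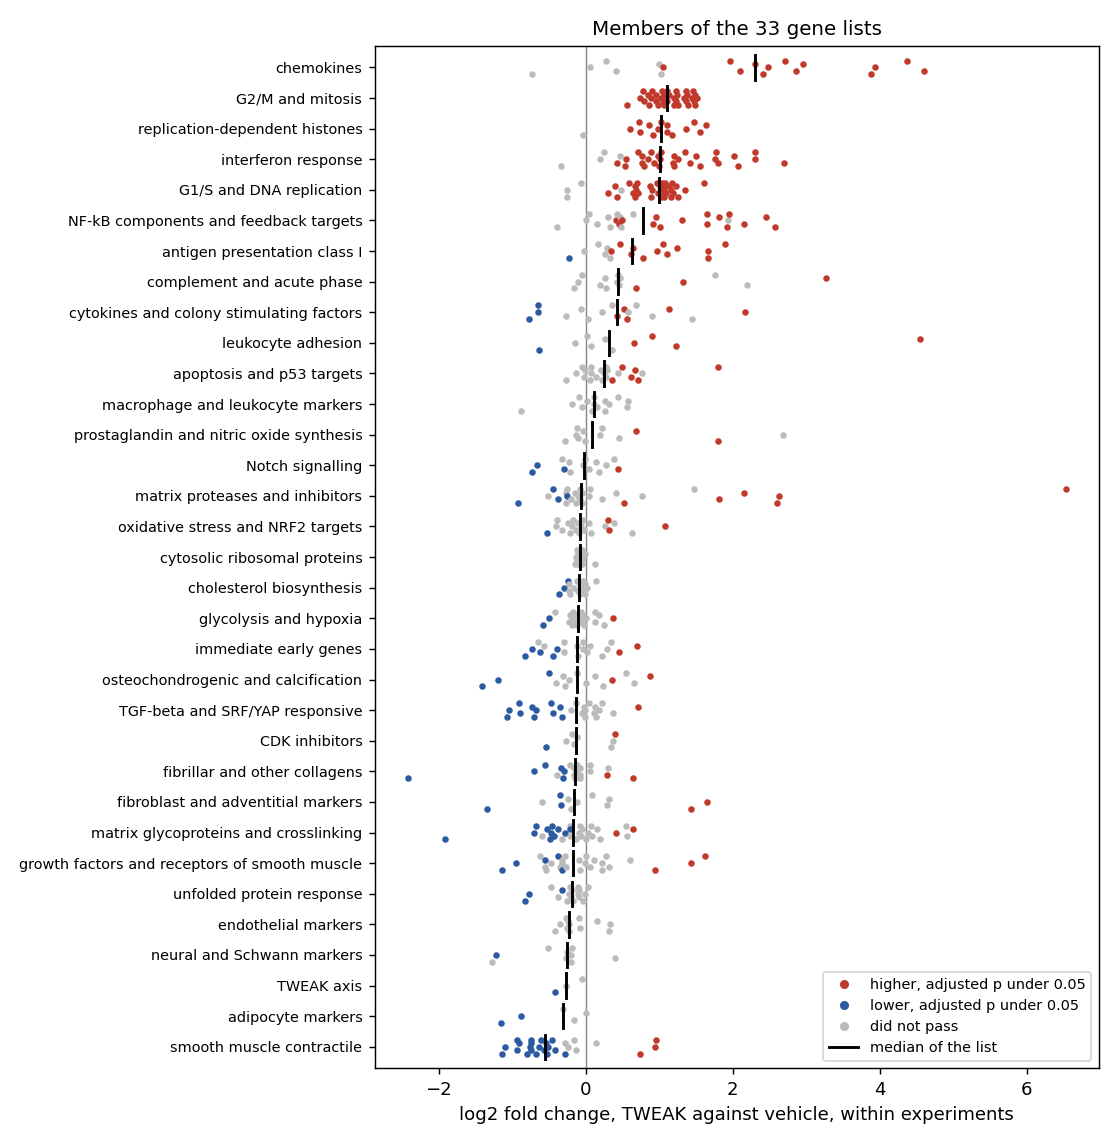
Log2 fold change of TWEAK against vehicle within experiments for each measured member of the 33 gene lists, with colour marking members higher or lower at an adjusted p under 0.05 in the blocked limma fit and black bars the list medians. The medians run from 2.30 for chemokines to -0.56 for contractile genes, and all 37 members of the mitosis list lie above 0.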

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

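The fits under the replicate block other than the plain one, the filter at a mean of 50 and the correction for GC content and length were chosen after the data were seen. The unpaired count of 3 genes changed by TWEAK became 2039 with the replicate block, 752 with DESeq2 on the recovered reads, 246 after the GC and length correction, 1 after cyclic loess scaling and 1 with edgeR and upper quartile scaling. At adjusted p under 0.01 it was 1 and at adjusted p under 0.1 it was 73, and without single libraries it ranged from 0 to 2. The count was 0 without vehicle replicate 3 and without each TWEAK library, where limma gave from 861 to 1396 genes at an unadjusted p under 0.05; other tools were not run there. The cause of these moves was not tested, except that fewer libraries were fitted where 1 was left out. The paired count of 2039 was 3 with no replicate block, 4175 after the GC and length correction, 679 at adjusted p under 0.01, 3288 at adjusted p under 0.1 and 595 with an absolute log2 fold change of at least 1. It ranged from 666 to 3902 without single experiments, being 695 without replicate 1, 3902 without replicate 2 and 666 without replicate 3. The 1210 paired higher genes were 3 with no replicate block, 507, 1820 and 460 at those thresholds in turn, and 506 to 1930 without single experiments. The 829 paired lower genes were 0 with no replicate block, 172, 1468 and 135 at those thresholds, 154 to 1972 without single experiments, 1383 with edgeR and upper quartile scaling, and 2386 after the GC and length correction; the causes were not tested. In the other paired settings the count of changed genes lay between 1746 with edgeR and 2949 with edgeR and upper quartile scaling. The filters of none and of a mean of at least 5 removed no gene and so test nothing. Cyclic loess moved the median log2 fold change of all genes by -0.04.

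The unpaired count of 18 lists fell to 1 with an estimated correlation and to 8 with fry. The paired count of 18 fell to 0 with an estimated correlation, a test that the simulated planted list did not pass either. Both stayed between 13 and 19 in the settings that kept the preset correlation. Under the block, the collagen, matrix glycoprotein and ribosomal lists passed as deposited and not after cyclic loess scaling. The ribosomal list did not pass after the GC and length correction either (camera adjusted p = 0.138). The causes were not tested. Of the 147 genes named here that the paired fit called, 133 were called in every paired setting that kept 3 experiments, the threshold and the gene. There were 13 such settings, and 12 for Ccdc42 and Ntng1, whose means were under 50. At adjusted p under 0.01 93 passed and at an absolute log2 fold change of at least 1 85 did, and all 147 kept their direction in every paired setting that kept them. Sign changes of log2 fold changes were met by genes that the unpaired fit did not call. Without single libraries, Tnc ranged from -0.82 to 0.10, Cp from -0.15 to 1.67, Bdnf from -0.77 to 0.014, Pecam1 from -1.13 to 0.64, Cdh5 from -0.95 to 0.74, Lyz2 from -1.23 to 1.10, Mpeg1 from -1.10 to 1.81 and Col1a2 from -0.19 to 0.018. Lyz2 was 0.0018 with edgeR, and Mpeg1 was -0.019, -0.026 and -0.029 with edgeR's 3 normalizations and -0.026 with DESeq2. Under cyclic loess scaling, blocked or not, Rplp0 was 0.054, Rps2 0.052, Col1a2 0.14 and Col3a1 0.066. Leaving out 1 library leaves its experiment without a partner; the cause was not tested further. Each library held 62632273 reads or more, and whether depth limited the calls was not tested.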

Other observations

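Every gene family and gene of this paragraph was chosen after its values were seen. All 6 listed members of the Serpina3 family of serine protease inhibitors rose, with a median log2 fold change of 3.29; Serpina3h rose 11.1-fold from 120 ± 59.4 to 1269 ± 382 normalized counts and Serpina3i 8.67-fold (SD, n = 3). With edgeR on the recovered reads 5 of the 6 rose, and with cyclic loess, median-ratio and upper quartile scaling all 6. All 4 Id genes, inhibitors of DNA binding that BMP signalling induces, fell under each of these scalings, Id4 by 1.25 and Id1 by 0.89 on the log2 scale. Among the 7 guanylate-binding protein genes, 6 rose under each of them. Of 58 histone symbols, 47 rose and none fell, with 1 that fell under cyclic loess and under upper quartile scaling. Of 93 ribosomal protein symbols none passed in limma (5 at an unadjusted p under 0.05) or edgeR, while 2 fell under upper quartile scaling and 18 after the GC and length correction. Dclk1, a microtubule-associated kinase, rose 5.83-fold from 7921 ± 3286 to 44858 ± 15364 normalized counts (limma adjusted p = 0.00276), with log2 ratios of 2.33, 2.75 and 2.54 in the 3 experiments. Enpp2, the enzyme autotaxin, rose 4.70-fold. Single genes that fell, with no list tested for them, were the alpha-1D adrenergic receptor gene Adra1d by 1.30, the thromboxane receptor gene Tbxa2r by 1.01 and F3, tissue factor, by 1.00 on the log2 scale, and Aldh1a3, which makes retinoic acid, by 1.38.

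The experiments differed in the level of genes of other cell types, values that were looked at after the data were seen. All 15 macrophage and leukocyte markers differed among experiments, with a median level 2.75 log2 units above the mean of all libraries in experiment 1, and at -0.59 and -1.78 units in experiments 2 and 3. Of 12 endothelial markers 11 differed, with median levels of -1.65, 1.27 and 0.35. Of 28 contractile genes 16 differed, with median levels of 0.19, -0.14 and -0.05. Lyz2 had 35968 and 36137 normalized counts in the vehicle and TWEAK libraries of experiment 1, 5831 and 5567 in experiment 2, and 1866 and 1743 in experiment 3. Cdh5 had 1911 and 1885, 16217 and 14724, and 8029 and 7479.

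Of the tests that follow, the correlation of libraries of one experiment, the test on markers of other cells and the test on the share of smooth muscle cells were chosen after the result was seen.

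The blocked fit called 2039 genes and the unpaired fit 3. Differences shared by both libraries of an experiment may account for this, since the lowest of the 3 correlations of deviations within an experiment was 0.734. A single experiment carrying the calls is argued against: of the 500 genes with the smallest p in 2 experiments, at least 98.8% moved the same way in the experiment left out. Of the 10 splits of the 6 libraries into 3 and 3, only the real 1 gave as many genes unpaired. It gave 3, against a highest other of 0, where limma gave up to 2866 genes at an unadjusted p under 0.05. Of the 4 splits that part all experiments, only the real 1 gave 2039. The highest other was 0, with up to 214 genes at an unadjusted p under 0.05. The other splits mix vehicle and TWEAK libraries on each side, so a TWEAK effect adds to their residual spread. Few calls there would follow from any such effect and do not measure chance. For lists, 2 of the 10 splits reached the real 18 unpaired, since the split of vehicle libraries 1 and 3 with TWEAK library 1 against the rest gave 20, a split that sets experiment 1 apart from experiment 2, and with the block the real split gave 18 and the highest other 11 (1 of 4); these splits are too few for a share under 0.05.

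Genes of replication and mitosis were higher with TWEAK. GC content or transcript length as the whole cause is argued against by the corrected median of the mitosis list, 1.04, with all 37 members still higher. More endothelial, macrophage, adipocyte or neural cells are argued against by their marker lists. Their highest upper quartile was 0.29 (macrophages), below the lower quartile of 0.96 of the mitosis list. For fibroblasts the upper quartile of 0.30 cannot decide this, since Dpt and Pdgfra rose by 1.64 and 1.44 while 3 other markers fell. A hypothesis that remains is that more cells may have been in the cell cycle with TWEAK. The vehicle libraries also held transcripts of dividing cells (Ccna2, 3273 normalized counts on average), and a count of cells in the cycle, which could decide this, was not analysed here.

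Of 28 contractile genes, 20 were lower with TWEAK and 3 higher. The list passed camera with the preset correlation and not with an estimated one. A lower share of smooth muscle cells need not raise all other markers alike, since growth of any other cell type alone would lower it. A rise of all 5 other types alike is argued against by their markers moving apart. The lowest upper quartile of the 5 marker lists was -0.20 (neural and Schwann markers). It lay below 0 and below the highest lower quartile of -0.02 (macrophages). Whether the share of smooth muscle cells was lower cannot be decided from these lists. A change in fibroblasts alone stays open, as Dpt and Pdgfra rose by 1.64 and 1.44 on the log2 scale while 3 other markers of the list fell. GC content or transcript length as the whole cause is argued against by the corrected median of -0.57, with 21 of 28 members lower. A change of expression within the smooth muscle cells may remain as a hypothesis, and whether dividing and contractile states were in the same cells cannot be read from bulk RNA.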
